A study of Mus musculus with 2 samples.

How the data were processed

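The series holds 2 DNase-seq libraries of heart tissue from male B6CASTF1/J mice aged 18 to 20 months, per the labels, numbered biological replicates 1 and 2 and treated as 1 group. They come from separate tissue records under 1 shared donor record, so whether they are from different animals is not given in the sources used here. For each library the authors deposited 2 lists of narrow peaks, a list of footprints and a track of the FDR of the cut rate, all on the mouse assembly mm10 and derived from filtered alignments of that library, per the deposited readme files. Peaks and footprints were thus called per library and not on pooled reads. The aligner, the peak and footprint callers, their versions and thresholds are not given in the sources used here.

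The deposited peak lists give 1 signal value per peak. Within each library every signal was a whole multiple of 1 step, 0.00526 in replicate 1 and 0.00532 in replicate 2, with 100% of values within 0.05 of a step, as counts divided by a factor would give, but the scaling is not stated and read totals are not in the files. The depth is therefore unknown and signals were compared mainly within a library. The other numeric columns of the peak lists are constants and were not used. The deposited cut-rate track gives an FDR, an adjusted p-value, for each run of bases, from 0 to just under 0.05. The deposited footprint lists carry the constant 0.01, read as the FDR threshold of the calls, so footprints could not be ranked.

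The stricter peak list was the main list, by a rule fixed before the data were examined, as were the gene lists, motifs, tests, named genes and alternatives unless said otherwise. The files do not state the thresholds of the lists, so they were told apart by the track. The lowest FDR inside each peak stayed below 0.001 in the main list (at most 0.000991 in replicate 1 and 0.000998 in replicate 2). In the other list, of 185996 and 173255 peaks, it reached 0.0499 and 0.05.

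Genes and starts came from GENCODE M21, and sequence from the matching mm10 reference, over the 19 autosomes, X and Y. A promoter peak overlapped 1 kb either side of any annotated transcript start, and a linked peak had its midpoint in the gene body or 10 kb either side, so that neighbouring genes can share a peak. Shared peaks overlapped by at least 1 bp, and signals were paired by the largest overlap. Random expectations came from 20 draws of positions on the same chromosome, or for footprints inside the same peaks. Shares have exact 95% Clopper-Pearson intervals and counts exact Poisson intervals. Ratios of motif rates have intervals of the Poisson kind. All of these cover counting error only, and neighbouring peaks are not independent. Means ± SD are over n = 2 libraries. Promoter signal was higher in replicate 2, by a median log2 ratio of 0.454 over 14485 genes. The SD of a promoter signal therefore includes this offset and does not measure reproducibility alone. There is no second group, so no test between groups was possible and no p-value is given.

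There were 19 gene lists with 323 entries. They were cardiomyocyte sarcomere, cardiac ion handling, cardiac transcription factors, natriuretic peptides and stress genes, oxidative metabolism, endothelial, fibroblast, smooth muscle and pericyte, macrophage, lymphocyte, epicardial and mesothelial, adipocyte, Schwann cell, erythroid, skeletal muscle, hepatocyte, neuron, germ cell and housekeeping genes. For each list the share of members with a promoter peak and the mean number of linked peaks were placed among 10000 random lists of protein-coding genes of the same size, matched on deciles of gene span. A list stood above or below when it was past percentile 97.5 or under percentile 2.5 in both libraries. The percentiles describe these libraries, since genes are not replicates, and they are not corrected for the 38 comparisons of 19 lists on both measures.

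Each of 30 fixed consensus motifs was searched on both strands, and a site counted where its centre lay, so that part of it can lie outside a footprint. Its sites per kb in footprints were compared with those in the remaining bases of the same peaks, and a motif was called enriched when its interval lay above 0 and its ratio was at least 1.5-fold in both libraries. A consensus is shared by many factors and names none of them, and a count of 0 in a control was set to 3, which makes the ratio a lower bound. The named genes were, from each list, the 3 with the highest and the 1 with the lowest mean number of linked peaks, the 10 genes with the most linked peaks per 10 kb among those with at least 10 in both libraries, the 10 strongest peaks with their nearest gene, and Nppa, Nppb, Myh6, Myh7 and Gata4. A part of them is printed with values. The genes named on the Y chromosome and the footprints described at single genes were chosen after their values were seen.

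Alternatives were the other peak list, peaks above the median signal, equal numbers of peaks, 50% reciprocal overlap, promoter windows of 500 bp and 2500 bp, a window of 50 kb around the gene start, leaving out promoter peaks, unmatched random lists, the reversed motif as control, FDR limits of 0.05 and 0.01, and leaving out each library. The overlap, pairing, list and motif functions were tested on simulated data. Of 100000 simulated peaks 80296 overlapped a partner, as in bedtools 2.31.1, and a planted Pearson r of 0.9 was found as 0.898. Of 200 simulated lists of 18 genes drawn from 21911 genes, linked peaks placed 3.5% above with no change, 32% with a 1.5-fold rise and 74.5% with a 2-fold rise. All 9 planted motif settings had the planted value in their interval. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Variants of the CAST/EiJ genome against the reference, and raw reads, were not analysed here.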

Results

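Open chromatin was mapped by DNase-seq, which sequences DNA cut by the nuclease DNase I in isolated nuclei, in heart tissue of adult male mice of the strain B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ, aged 18 to 20 months. The 2 libraries form 1 group and are biological replicates 1 and 2 from separate tissue samples that share 1 donor record in the labels. There is no second tissue, age or treatment, so the comparisons are between the replicates and between parts of the genome within each library. Replicate 1 held 127634 peaks covering 25.5 Mb and replicate 2 held 116387 peaks covering 22.8 Mb (mean 122010 ± 7953 peaks, SD, n = 2), which is 0.934% and 0.838% of the chromosomes. The median peak was 200 bp wide in replicate 1 and 199 bp in replicate 2. The files carry no read totals, so the sequencing depth is unknown, and peak signal is in the scaled unit of the deposited lists, whose scaling is not stated.

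Genes of the working heart muscle had open promoters in both libraries. Of 20 genes of the cardiomyocyte sarcomere, the contractile unit of muscle, 18 had a peak within 1 kb of a start in replicate 1 and 19 in replicate 2, against a median of 70.0% in random gene lists of the same size and gene length. All 24 genes of oxidative metabolism did so in both libraries. Of 12 natriuretic peptide and stress genes 11 did so in each library, 10 of them in both, and of 22 cardiac transcription factor genes 20 in replicate 1 and 21 in replicate 2. These lists lay at or above percentile 98.1 of the random lists in replicate 1 and percentile 99.1 in replicate 2. Among members with a promoter peak the median signal was 3.26 units in replicate 1 and 3.20 in replicate 2 for sarcomere genes and 1.85 and 1.91 for natriuretic peptide and stress genes, below the medians of 6.20 and 8.76 over all genes with such a peak, and it was 6.19 and 7.65 for cardiac transcription factor genes and 7.31 and 10.7 for oxidative metabolism genes. Myom1, which encodes a protein of the sarcomere M-band, had the strongest promoter peak of the named sarcomere genes, at 26.1 ± 5.54 signal units (SD, n = 2), whereas Ldb3 was at 3.70 ± 0.615 and Tnnt2 at 3.03 ± 0.628. Ppara, a nuclear receptor that controls fatty acid oxidation, was at 12.3 ± 2.91, Tead1, a transcription factor gene, at 9.53 ± 3.50, and Rcan1, an inhibitor of calcineurin, at 19.9 ± 2.41. The cardiac ion handling genes had promoter peaks at 18 and 17 of 20 members, at percentiles 95.5 and 84.7, which did not set the list apart. The call of the transcription factors was lost in the longer, less strict peak list (percentile 96.5 in replicate 1), and that of the natriuretic peptide and stress genes was lost against random lists not matched on gene length (96.7 and 96.5).

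The promoters of the other main cell types of heart were open as well. All 20 endothelial and all 20 fibroblast genes had a promoter peak in both libraries, as did 15 and 14 of 15 smooth muscle and pericyte genes in replicates 1 and 2, and these 3 lists stood above the random lists in both. Their median promoter signals lay below those over all genes, at 3.65 and 4.81 units for endothelial, 2.74 and 3.95 for fibroblast and 1.58 and 2.08 for smooth muscle and pericyte genes. The named genes with the highest promoter signal were Flt1, a receptor of vascular endothelial growth factor, at 6.67 ± 1.67 units (SD, n = 2), Col5a1, a collagen gene, at 5.93 ± 1.56, and Mylk, the smooth muscle myosin light chain kinase, at 5.33 ± 1.89, and those with the lowest were Pecam1, an adhesion molecule of endothelium, at 2.65 ± 0.603, Lum at 0.624 ± 0.0428 and Abcc9 at 1.59 ± 0.403. All 16 housekeeping genes had a promoter peak in both libraries and stood above the random lists, with Actb at 23.5 ± 4.32 and Gapdh at 19.1 ± 2.94. Macrophage genes had promoter peaks at 17 of 19 members in replicate 1 (percentile 99.4) and 15 in replicate 2 (percentile 91.8), and lymphocyte genes at 11 of 17 (37.3) and 7 of 17 (0.81), so neither list was called in both libraries. Spi1, the gene of the myeloid factor PU.1, had a promoter peak of 3.29 ± 0.230 units, and Cd3e, a T cell receptor chain, had no promoter peak. With peaks above the median signal alone, smooth muscle and pericyte genes fell to percentiles 94.9 and 84.4 and lost the call, and with a promoter window of 500 bp they were at 99.2 and 96.1.

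Markers of liver and germ cells had few open promoters. Only 4 of 18 hepatocyte genes in replicate 1 and 3 in replicate 2 had a promoter peak (22.2% and 16.7%, against 61.1% in random lists), and of 14 germ cell genes 4 and 3 had one (28.6% and 21.4%, against 64.3%). Alb, the serum albumin gene, and Sycp1, a gene of the meiotic synaptonemal complex, had no peak within 10 kb of the gene in either library, whereas Tex14, a germ cell gene, had a promoter peak of 12 ± 3.53 units (SD, n = 2). The germ cell call was lost in the less strict peak list, at percentiles 0.855 and 3.15. Lists that were not called in both libraries were skeletal muscle (9 and 8 of 19), neuron (11 and 12 of 18), epicardial and mesothelial (7 and 7 of 12), adipocyte (5 and 6 of 12), Schwann cell (7 and 7 of 12) and erythroid genes (5 and 5 of 13). With a window of 500 bp the skeletal muscle list was below the random lists at percentiles 0.05 and 0, and the neuron list at 0.445 and 1.63. With peaks above the median signal alone the neuron list (0.02 and 0.205), the lymphocyte list (1.57 and 0.375) and the epicardial and mesothelial list (0.64 and 0.595) were below, as was the erythroid list against unmatched random lists (1.78 and 1.70). The epicardial and mesothelial list went the other way in the less strict peak list. There 10 and 12 of its 12 members had a promoter peak, at percentiles 82.7 and 99.4, so its place depends on the peak threshold. In all, 8 of the 19 lists stood above and 2 below the random lists in both libraries. Over all 21911 protein-coding genes, 14770 had a promoter peak in replicate 1 (67.4%) and 14843 in replicate 2 (67.7%), 14485 in both and 6783 in neither.

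**Figure D1:**
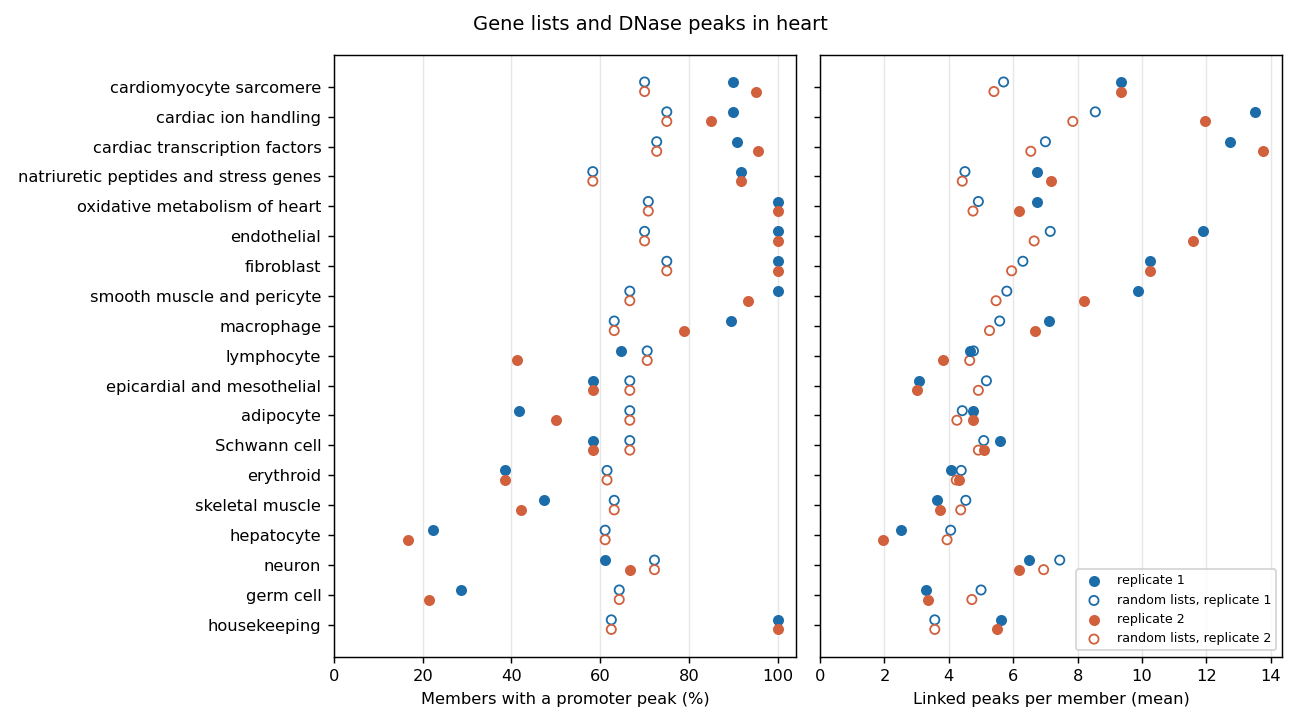
Share of the members of each gene list with a promoter peak (left, in percent) and mean number of peaks in the gene body and 10 kb either side (right), for each library. Filled points are the lists and open points the medians of 10000 random lists matched on gene length; the 24 oxidative metabolism genes sit at 100% in both libraries and the hepatocyte genes at 22.2% and 16.7%.

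Cardiac regulators were also rich in peaks around and inside the gene. The 22 cardiac transcription factor genes had a mean of 12.7 linked peaks per gene in replicate 1 and 13.8 in replicate 2, counted over the gene and 10 kb either side, against random medians of 7.0 and 6.55. The endothelial genes (11.9 and 11.6, against 7.15 and 6.65), the fibroblast genes (10.3 and 10.3, against 6.30 and 5.95) and the sarcomere genes (9.35 and 9.35, against 5.70 and 5.40) also stood above the random lists in both. Counts of single genes follow gene length as well. Cacna1c, the pore subunit of the cardiac L-type calcium channel, which spans 609179 bp, had 59 peaks in replicate 1 and 52 in replicate 2, but a mean of only 6.5 within 50 kb of its start. Esrrg, an orphan nuclear receptor gene of 606095 bp, had 37 and 31, with 8.5 near its start, and Slc8a1, the sodium-calcium exchanger, of 365273 bp, had 36 and 19, with 8 near its start. Kcnq1, a potassium channel gene, had 34 and 36, with 22 near its start, Tead1 34 and 36, with 18, and Hand1, of 4114 bp, had 1 in each library, with 9.5. Among the vascular and stromal genes, Flt1 had 27.5 ± 3.54 peaks (SD, n = 2), with 18 within 50 kb of its start, Pecam1 24.5 ± 0.707, with 20, Col5a1 24.5 ± 2.12, with 19, and Mylk, of 257211 bp, 27.5 ± 4.95, with 4.5. Hepatocyte genes had fewer linked peaks than random lists (2.5 and 1.94, against 4.06 and 3.94). Of the 19 lists 4 stood above and 1 below in both libraries, replicate 1 alone placed 7 above and replicate 2 alone placed 4 above. Counting peaks within 50 kb of the gene start placed 8 above. Without promoter peaks the sarcomere call was lost (percentiles 95.4 and 97.7), in the less strict peak list the endothelial call was lost (98.0 and 97.2), and the hepatocyte call was lost in both of these settings and with the window of 50 kb.

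The remaining lists did not stand apart by linked peaks in both libraries, and their members differed widely. Cardiac ion handling genes had 13.5 and 11.9 linked peaks per gene (percentiles 97.8 and 96.9), smooth muscle and pericyte genes 9.87 and 8.20 (98.1 and 93.8), and housekeeping genes 5.63 and 5.50 (98.4 and 96.2). Natriuretic peptide and stress genes had 6.75 and 7.17, oxidative metabolism genes 6.75 and 6.17, and macrophage genes 7.11 and 6.68. Cx3cr1, the fractalkine receptor gene, annotated over 168264 bp, had 32 peaks in replicate 1 and 36 in replicate 2. Its promoter signal was only 0.555 ± 0.0197 units (SD, n = 2). Adgre1, the gene of the macrophage marker F4/80, of 124837 bp, had 1 peak in each. Lymphocyte genes had 4.65 and 3.82, with 11 and 8 at Cd28, and skeletal muscle genes 3.63 and 3.74, with 11 and 10 at Ryr1 and 0 at Myf5. Neuron genes had 6.50 and 6.17, germ cell genes 3.29 and 3.36, erythroid genes 4.08 and 4.31, Schwann cell genes 5.58 and 5.08, adipocyte genes 4.75 and 4.75, and epicardial and mesothelial genes 3.08 and 3.0. Some of these lists were called under an alternative. Cardiac ion handling genes stood above in the less strict peak list (percentiles 98.2 and 98.1). With peaks above the median signal alone, oxidative metabolism (98.7 and 97.7) and housekeeping genes (99.5 and 99.6) stood above, and epicardial and mesothelial genes (0.04 and 0.33) below. The protein-coding genes with the most linked peaks per length were Cd151, a tetraspanin gene, with 23 and 27, its neighbours Cracr2b, with 24 and 26, and Polr2l, with 18 and 29, and Midn, with 28 and 29. Actg1, Pnpla2, Bcl9l, Crip2, Crip1 and Dapk3 completed the 10 densest, and Bcl9l had 43 and 49. Cd151, Polr2l, Cracr2b and Pnpla2 lie side by side on chromosome 7 and share peaks.

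The myosin heavy chain genes of cardiomyocytes lie side by side on chromosome 14 and differed at their starts in the main peak list. Myh6, the main myosin heavy chain of the adult mouse ventricle (mm10, 54941921 to 54966927, reverse strand), had 8 linked peaks in each library and a promoter peak of 3.33 ± 0.184 units (SD, n = 2). Myh7, the slow isoform that dominates before birth (54970684 to 54994626), had 7 peaks in replicate 1 and 6 in replicate 2 and no peak within 1 kb of its start in either. In the less strict peak list all 20 sarcomere genes, Myh7 among them, had a promoter peak in both libraries, so this absence depends on the peak threshold. The promoter peak of Myh6 and the peaks between the 2 genes are linked to both genes and counted for each. The strongest peak of the region lay between the 2 genes, at 54968401 to 54968700 in replicate 1, with signals of 4.33 and 4.38. Upstream of Myh7, a peak at 55003901 to 55004240 had signals of 3.22 and 3.76. A MEF2 motif at 55004113 to 55004122 in this peak reached across the edge of a footprint of each library, with its centre inside the footprint of replicate 1 and outside that of replicate 2. Of the 22 footprints in replicate 1 peaks linked to Myh7, 15 overlapped a footprint of replicate 2. The 22 include the footprints in the peaks shared with Myh6, among them 8 in the Myh6 promoter peak.

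**Figure D2:**
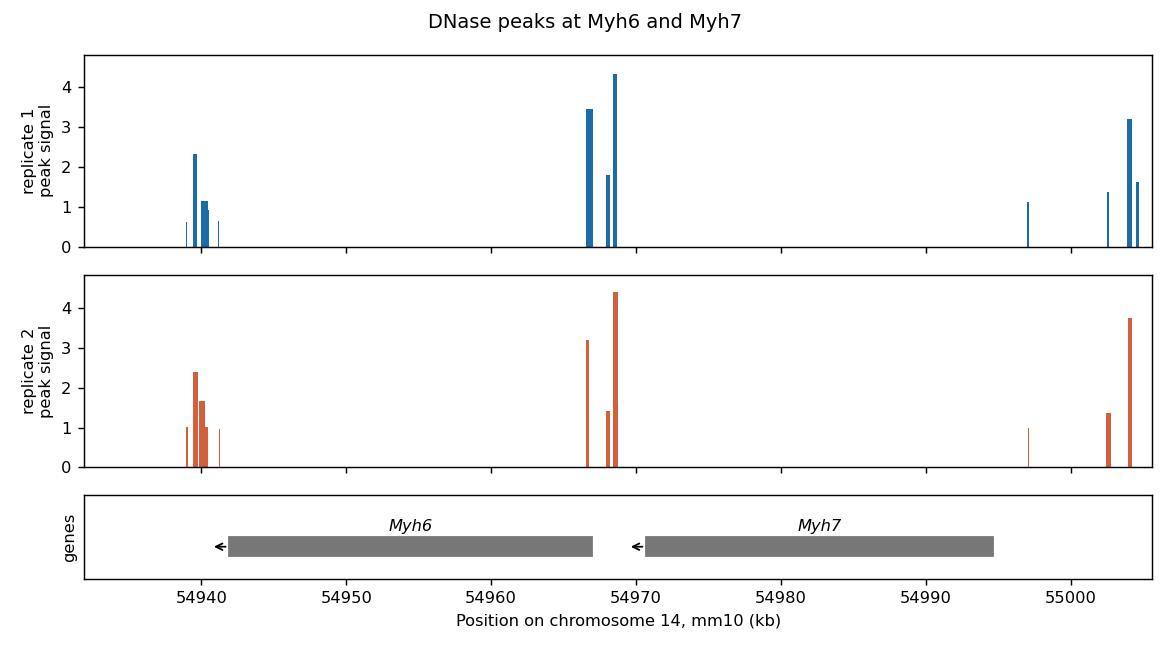
Peaks of the main list at Myh6 and Myh7 in replicate 1 (top) and replicate 2 (middle), with position on chromosome 14 in kb on the horizontal axis and peak signal on the vertical axis. Grey boxes are the genes and arrows give the direction of transcription; the tallest bars, between the genes, reach 4.33 and 4.38, and no bar stands at the start of Myh7.

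Natriuretic peptide genes had weak promoter peaks. Nppa, atrial natriuretic peptide (chromosome 4, 148000722 to 148002079, forward strand), had a promoter peak of 0.463 units in replicate 1. In replicate 2 it had none in the main list but at least 1 in the less strict list. Nppa had 3 and 2 linked peaks. Its strongest linked peak had signals of 0.846 and 1.00 and held a footprint with a whole CTCF motif in both libraries, AGGAGGTGCCCCCTGCTGGACTGG at 148008572 to 148008595 in replicate 1. Nppb, brain natriuretic peptide (147985788 to 147987205), had 2 peaks in each library, both within 1 kb of its start, the stronger at 1.15 ± 0.0136 units (SD, n = 2). Gata4, a zinc finger factor of heart development (chromosome 14, 63198922 to 63271692, reverse strand), had 19 peaks in replicate 1 and 14 in replicate 2, and its strongest promoter peak, at an annotated start inside the gene, had a signal of 7.06 ± 1.69. In this peak the centre of an SP/KLF motif lay inside a footprint of both libraries, and the footprint lay 71 bp from the start. Of 45 footprints in Gata4 peaks of replicate 1, 28 overlapped one of replicate 2.

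The peaks with the highest mean signal over both libraries lay at annotated starts. The first was on chromosome 17 at 6430001 to 6430180, 21 bp from a start and nearest to Dynlt1b, a dynein light chain gene, with signals of 59.0 and 79.9. Next were Hjurp, a histone chaperone of centromeres (52.2 and 69.6), Dnpep (41.7 and 56.9), Gm21887 near the end of the X chromosome (31.1 and 59.4) and a peak on chromosome 17 in the annotated locus CT010467.1 (35.6 and 50.9), whose nearest protein-coding gene, Esp38, starts 103669 bp away. Bahcc1 (36.3 and 48.9), Ankhd1 (38.1 and 45.5), Mplkip (34.8 and 45.7), Peak1 (33.2 and 45.3) and Fzr1 (33.1 and 44.7) followed, all with the peak within 1 kb of a start. The peak at Gm21887 was weaker than these in replicate 1 and owes its place to replicate 2, and all 300 of the 36-bp sequences that start in it also occur on Y. Among peaks in the top decile by signal, 78.3% in replicate 1 and 83.0% in replicate 2 were promoter peaks.

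Promoters held more peaks than random positions give, and stronger ones. The share of peaks within 1 kb of an annotated start was 27.1% in replicate 1 (95% Clopper-Pearson interval 26.89 to 27.38) and 29.7% in replicate 2 (29.43 to 29.95), against 6.71% and 6.72% for shuffled positions. Introns held 38.2% and 36.7% of peaks, exons 4.27% and 4.62%, and intergenic sequence 30.4% and 29.0%. The median signal of promoter peaks was 2.06 times that of the others in replicate 1 (1.71 against 0.831) and 2.25 times in replicate 2 (2.20 against 0.979).

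Footprints, the short stretches inside open chromatin that are cut less than their surroundings, numbered 469598 in replicate 1 and 478231 in replicate 2 (mean 473914 ± 6104, SD, n = 2), with a median width of 10 bp in each. CTCF and NRF1 had the highest ratios of the 30 fixed motifs. The motif of CTCF, the insulator protein, was more frequent in footprints than in the rest of the same peaks by a log2 ratio of 5.82 in replicate 1 (95% interval 5.67 to 5.97) and 6.30 in replicate 2 (6.11 to 6.48), from 4779 and 4924 sites. NRF1, a regulator of nuclear genes of mitochondria, was at 5.69 and 5.59, NFI at 5.0 and 5.18, the cyclic AMP response element at 4.60 and 4.50, RFX at 4.34 and 4.42, CEBP at 3.78 and 3.80, SP/KLF at 3.49 and 3.53, and ETS at 2.97 and 3.10. The nuclear receptor DR1 motif was at 2.88 and 1.90, from 33 and 25 sites, YY1 at 2.38 and 2.62, a part of the REST site at 1.15 and 1.5, and the muscle E-box, the site of myogenic and other bHLH factors, at 0.71 and 0.75. These were the 12 of 30 fixed motifs enriched in both libraries. The same 12 were enriched in peaks outside promoters. Set against the reversed motif inside footprints alone, 21 motifs were past the same threshold, without SP/KLF (0.26 in each library), but a motif and its reversal can differ in frequency in any sequence. The reversed sequences of some motifs were themselves more frequent in footprints than in the rest of the peaks, at 3.75 and 3.67 for NRF1 and 3.12 and 3.14 for SP/KLF. Reversal keeps the base composition but not the CG pairs (C followed by G). The reversed NRF1 motif still has such pairs, while the cyclic AMP response element and ETS motifs lose theirs. The differences between motif and reversed motif thus do not by themselves rank these motifs. With the log2 ratio of the reversed motif subtracted, NRF1 was at 1.94 and 1.92. CTCF, with 3 and 2 reversed sites in footprints, was at 5.40 and 6.20. NFI also had few reversed sites (95% intervals of the difference 2.26 to 8.58 and 2.36 to 8.84). The cyclic AMP response element was at 4.99 and 4.70, CEBP at 3.62 and 4.26 and ETS at 3.37 and 3.26. SP/KLF was at 0.37 and 0.40, under 1.5-fold, and the part of the REST site at 0.64 (95% interval -0.20 to 1.47) and 1.58 (0.66 to 2.49). The nuclear receptor DR1 motif was at 2.46 (95% interval 0.43 to 4.49) and 3.46 (0.40 to 6.52), with 3 and 1 reversed sites. YY1 was at 1.92 (0.99 to 2.84) and 3.33 (2.29 to 4.37), and the muscle E-box at 0.88 and 0.92. For RFX the reversed motif had 0 sites in footprints, so that no difference was computed.

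Motifs of several cardiac factors did not reach the threshold of enrichment in footprints against the rest of the peaks. GATA was less frequent in footprints than in the rest of the peaks, at -1.07 (95% interval -1.12 to -1.02) in replicate 1 and -1.25 (-1.31 to -1.20) in replicate 2, and NKX2 at -0.51 and -0.61. MEF2 was at -0.27 (-0.39 to -0.16) and -1.07 (-1.24 to -0.91), so that the intervals of the replicates did not overlap. TEAD was at 0.02 and -0.13, SRF at 0.34 and -0.16, TBX at -0.58 and -0.54, and ESRR at 0.29 and 0.23. The E-box CATCTG, a site of HAND and other bHLH factors, was more frequent in footprints, at 0.44 (0.39 to 0.48) and 0.25 (0.21 to 0.30), and at 0.62 and 0.41 in peaks outside promoters, but below 1.5-fold in at least 1 library. FOX was the lowest, at -1.94 and -2.14, and PU.1 was at -0.45 and -0.62. With the log2 ratio of the reversed motif subtracted, the E-box CATCTG was at 1.502 and 1.410, TEAD at 0.76 and 0.65, ESRR at 0.48 and 0.79, PU.1 at 1.02 and 1.06, NKX2 at 0.06 and 0.20, GATA at -0.22 and -0.20, TBX at -0.48 and -0.31 and FOX at -1.39 and -1.53, while SRF was at 0.36 (95% interval 0.06 to 0.66) and 0.09 (-0.25 to 0.43) and MEF2 at 0.63 (0.30 to 0.97) and -0.13 (-0.52 to 0.26). The reversed GATA sequence can overlap the motif, as in AGATAGA, so the GATA difference is not a clean control for composition. The liver motif HNF1 had 0 sites in the peaks of either library. Of the 30 motifs, 9 had intervals below 0 in both libraries. The bases of footprints were 60.004% and 62.1% G or C, and the rest of the peaks 53.0% and 54.4%.

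**Figure D3:**
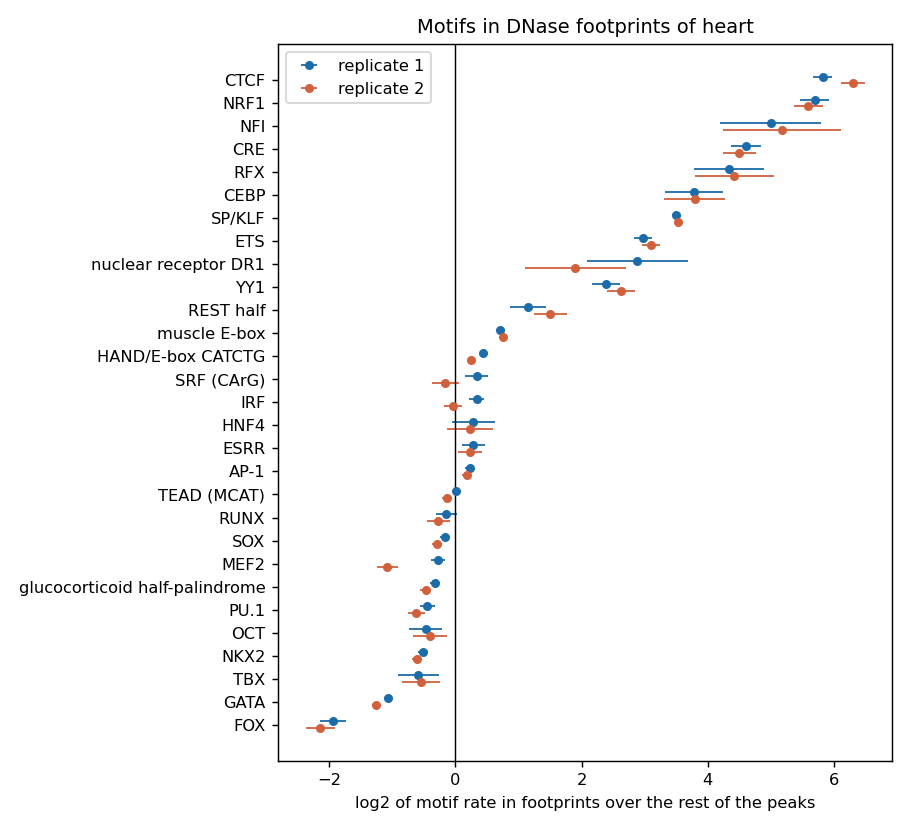
Log2 ratio of motif sites per kb in footprints to those in the rest of the same peaks (horizontal axis) for each fixed motif with sites (vertical axis). Points are the 2 libraries and bars 95% intervals for counting error; CTCF lies at 5.82 and 6.30 and FOX at -1.94 and -2.14.

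Most footprints lay in peaks, and part of them recurred at the same place. In replicate 1, 73.6% of footprints overlapped a peak, in replicate 2 69.6%, and 89.9% and 91.4% of peaks held at least 1 footprint, with 2.71 and 2.86 per peak. Of the footprints of replicate 1, 56.1% overlapped a footprint of replicate 2, and 53.8% in the other direction. Within peaks of both libraries the shares were 70.2% and 65.6%, against 39.6% and 37.4% when the other library's footprints were moved at random inside the peaks. Bases at an FDR of 0.001 in the cut-rate track covered 41.4 Mb and 38.6 Mb (mean 40.0 ± 2.04, SD, n = 2), of which 33.3 Mb were common, 80.4% of replicate 1 and 86.4% of replicate 2. At an FDR of 0.05 the mean was 60.2 Mb.

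The replicates shared most peaks and ranked them alike. Of replicate 1 peaks 79.1% overlapped a peak of replicate 2, and 86.9% in the other direction, against 1.84% and 1.99% for shuffled positions. Across 99970 paired peaks, which are not independent replicates, Spearman's rho was 0.935 and Pearson's r of log2 signal 0.958. The 26683 peaks of replicate 1 and 15236 of replicate 2 without a partner had median signals of 0.468 and 0.532, against 1.20 and 1.34 for shared ones. Of all main peaks, with or without a partner, 91.4% in replicate 1 and 94.6% in replicate 2 overlapped the other library's less strict list. In the top decile by signal 99.7% were shared in each library, and in the bottom decile 35.2% and 56.2%.

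The signal of replicate 2 was higher at promoters and at GC-rich sites. The median log2 ratio of replicate 2 to replicate 1 was 0.24 over all pairs (SD across peaks 0.43), 0.41 at promoter peaks and 0.14 at others. From the lowest to the highest of 5 equal bins of promoter peaks by GC content it went from 0.08 to 0.55, and among the other peaks from -0.14 to 0.35. Promoter peaks of sarcomere genes had a median log2 ratio of 0.03, those of macrophage genes 0.01 and of lymphocyte genes -0.11, against 0.48 for fibroblast, 0.39 for endothelial and 0.40 for housekeeping genes.

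**Figure D4:**
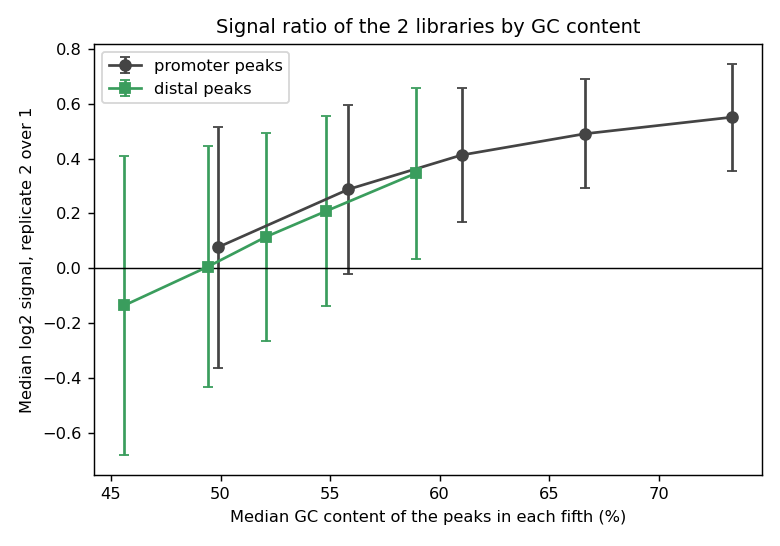
Median log2 ratio of peak signal, replicate 2 over replicate 1 (vertical axis), in 5 equal bins of shared promoter and distal peaks by GC content (horizontal axis, percent). Bars are the SD across peaks; the medians go from 0.08 to 0.55 in promoter peaks and from -0.14 to 0.35 in distal peaks.

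The X chromosome had fewer and weaker peaks than the autosomes. It held 17.7 peaks per Mb in replicate 1 and 15.7 in replicate 2, against 50.6 and 46.2 over the 19 autosomes, a ratio of 0.349 (95% exact Poisson interval 0.337 to 0.362) and 0.340 (0.328 to 0.353). The lowest autosome, chromosome 3, had 39.0 and 34.3 peaks per Mb and the highest, chromosome 11, had 73.9 and 71.1. The median signal of X peaks was 0.582 and 0.591 times the autosomal median, 0.655 and 0.628 times at promoter peaks. Of the 948 protein-coding genes on X, 49.9% and 49.8% had a promoter peak, against 68.8% and 69.1% on the autosomes, and X has 5.54 such genes per Mb against 8.44. With peaks above the median signal alone the mean density ratio fell from 0.345 to 0.222. This fall follows from the lower signal of X peaks, because the cut was the median over all chromosomes.

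**Figure D5:**
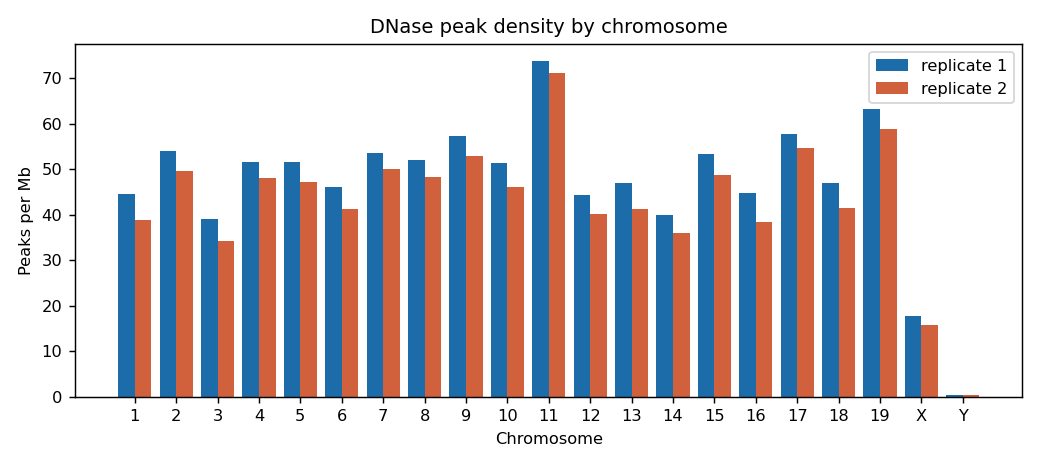
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) in the 2 libraries. The bars of X stand at 17.7 and 15.7, below the lowest autosome, chromosome 3, at 39.0 and 34.3.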

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

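No explanation was tested for the results of this part, technical or biological, and the search of Y peak sequences on X was chosen after these peaks were seen. In replicate 1, 123879 footprints, and in replicate 2, 145565, lay outside the main peaks and entered no comparison of motifs. They stand out as signal in data that the text has otherwise left aside. Of all footprints, 87.5% and 85.4% overlapped the less strict peak list, and 58546 and 69872 overlapped no peak of it.

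The Y chromosome, which was left out of the autosomal comparison, held 31 peaks in replicate 1 and 40 in replicate 2. In both libraries the starts of Kdm5d, Eif2s3y, Uty and Ddx3y, genes with X-linked partners, had a peak within 1 kb. The peak at Uty had signals of 4.21 and 4.12. Between 90717601 and 90744820, near Gm21860 at the distal end of the chromosome, replicate 2 had 20 peaks and replicate 1 had 1. The strongest of these had a signal of 7.76 in replicate 2 and 3.39 in replicate 1. The stretch lies beside the pseudoautosomal region, which Y shares with X. Of the 36-bp sequences that start in the 20 peaks of replicate 2, 11.3% also occur on X, and 59.5% of those in the strongest peak, so that the sequence does not assign all of this signal to Y. In the other Y peaks the shares were 22.8% in replicate 1 and 14.9% in replicate 2.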

How the results depend on the processing

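The promoter share at starts of protein-coding genes alone was chosen after the data were seen. Of 49 alternatives to the summary results 33 stayed within the replicate spread (for counts, within 1.5 times) and 16 moved further. The promoter share, 28.4%, was 24.4% in the less strict peak list, 38.8% with peaks above the median signal, 23.0% and 37.7% with windows of 500 bp and 2500 bp, and 24.5% at protein-coding starts. The promoter to distal signal ratio, 2.16, was 2.74 with 500 bp. Peaks shared by 50% reciprocal overlap were 75.2% and footprints 41.3%, against 83.0% and 55.0%. The X density ratio, 0.345, was 0.373 in the less strict list, 0.222 with peaks above the median signal and 0.319 without promoter peaks. Lists above by linked peaks were 8 with 50 kb around the start and ranged from 4 to 7 when either library was left out. Motifs past the threshold were 21 against the reversed motif, a comparison inside footprints alone, and 12 otherwise. The track covered 60.2 Mb at an FDR of 0.05 and 49.4 Mb at 0.01. A wider promoter window, a looser FDR limit and a stricter overlap fix by construction in which direction a share or a covered length moves. Taking peaks above the median signal must raise the promoter share and lower the X density ratio, because promoter peaks were stronger and X peaks weaker. For the other shifts, among them the signal ratio with 500 bp and the lists with 50 kb, the cause was not tested. Lists above by promoter peaks numbered 7 to 9 over all alternatives. Linked peaks of the named genes moved beyond the replicate spread in 297 of 546 alternatives. No paired analysis was possible because there is 1 group. Ranking footprints by score was not run, because the score is constant. The unknown depth limits any comparison of weak peaks, and n = 2 limits the SD.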

Other observations

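The tests of a single scale factor, of the cardiomyocyte share, of GC content list by list and of gene number on X were chosen only after the result was seen, and the requirement that the counting interval of a motif share exclude the random range was added after the shares were seen, as were the number expected by chance and the count of each peak once. Distal peaks, those over 1 kb from any start, held more sites of several motifs than windows 1000 bp to either side. CTCF stood at a log2 ratio of 6.19 in replicate 1 and 6.29 in replicate 2, NFI at 3.82 and 4.21, and CEBP at 3.32 and 3.54. The cyclic AMP response element was at 2.10 and 1.94, RFX at 1.91 and 1.98, ETS at 1.87 and 1.86, and NRF1 at 1.67 and 2.03. SP/KLF was at 1.64 and 1.82, with its reversed sequence at 1.53 and 1.67. PU.1 was at 1.64 and 1.44, the muscle E-box at 1.54 and 1.56, AP-1 at 1.42 and 1.36, and TEAD at 0.69 and 0.63. Distal peaks were 51.3% and 52.9% G or C and the flanks 44.6% and 45.1%, so each motif was set beside its reversed sequence. TEAD exceeded it by 1.01 and 0.93. MEF2 exceeded it by 2.22 and 2.11. Against the flanks MEF2 stood at 0.15 and -0.20, where its reversed sequence, of the same base composition, stood at -2.07 and -2.30. MEF2 sites themselves were thus not more frequent than in the flanks in both libraries. GATA (0.26 and 0.28), NKX2 (-0.03 and -0.02), SRF (0.40 and 0.29) and ESRR (-0.10 and -0.16) stayed below the 1.5-fold set in advance. So 2 of the 6 cardiac motifs passed, where at least 4 were asked for and at most 1 would have excluded it, which leaves the hypothesis that cardiac factor motifs mark these peaks open. Of the 29 motifs with sites, 14 passed. SP/KLF and GATA were not among them, but their reversed sequences can overlap the motif itself. Their small differences therefore cannot count against either motif.

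Motifs were also counted in the distal peaks linked to the gene lists. MEF2 sites lay in 7 of 108 such peaks of sarcomere genes in replicate 1 (6.48%, random median 3.39%) and in 5 of 111 in replicate 2 (4.50%, 2.35%), at percentiles 88.2 and 81.14 of random lists. ETS sites at endothelial genes lay in 1 of 173 and 2 of 166 peaks, at 62.75 and 78.8, and PU.1 sites at macrophage genes in 5 of 77 and 3 of 69 (5 of 69 and 3 of 63 with each peak counted once), at 87.5 and 73.78. None of the 3 stood above the random lists, and all 3 met the criterion set in advance for no excess, a share under percentile 90 in both libraries. The requirement added later was not met, because the upper 95% limits of the shares reached past the bound for standing above the random lists, as with 12.9% against 9.09% for MEF2 in replicate 1, so the counts are too few to exclude an excess and the hypothesis stays open. Of 95 pairs of list and motif, not corrected for their number, 1 stood above in both libraries, where 1.05 were expected from the random lists. This was MEF2 at germ cell genes, and its 3 of 14 and 3 of 16 came from 1 peak in each library that was counted at several neighbouring genes, so it gives no evidence of an excess.

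Replicate 2 had the higher signal, and at promoters its median log2 ratio exceeded that of distal peaks by 0.27, which argues against a single scale factor. GC content may account for much of it, since the fifth of distal peaks highest in GC exceeded the lowest by 0.48 and the gap between promoters and other peaks was 0.05 at equal GC. The 82 genes of the 6 lists picked for their low gain lay at -0.28 from random genes (SD of random lists 0.03) when matched on GC and signal, against -0.36 on signal alone. By list, the gap left with this matching was -0.36 for 18 sarcomere genes (SD 0.07, percentile 0). For 7 lymphocyte genes it was -0.55 (SD 0.12, percentile 0.02). Both lists were picked by the same ratios, which can enlarge such gaps, so they do not decide whether GC content is the whole cause. GC content as the whole cause also stays open for natriuretic peptide and stress (-0.24, percentile 2.21), oxidative metabolism (-0.10, percentile 2.04), macrophage (-0.25, percentile 3.39) and skeletal muscle genes (-0.18, percentile 7.95). A lower share of cardiomyocytes would raise the genes of other cell types. Macrophage and lymphocyte genes lay at -0.25 (SD 0.12, 15 genes) and -0.55 (SD 0.12, 7 genes). Both lists were among the 6 picked for their low gain, so they cannot decide it. With the same matching, other cell types lay on both sides of 0. Fibroblast genes were at 0.05 (percentile 77.1), adipocyte genes at 0.12 (88.2), endothelial genes at -0.01 (43.1) and smooth muscle and pericyte genes at -0.12 (6.95). The share of cardiomyocytes, a change in several cell types, the state of the animals and the unstated processing stay open.

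The X chromosome had fewer and weaker peaks than the autosomes. Per protein-coding gene, X still had 0.525 times as many peaks, so fewer genes do not account for it alone. With 1 copy in male cells, X peaks above a signal would match autosomal peaks above 2 times that signal, but at the median signal of X peaks their density was 0.397 times as high (mean of the libraries), and 0.605 times after division by the ratio of gene densities (0.657). From the lower to the upper quartile of X signal the first ratio rose from 0.378 to 0.449 in replicate 1 and from 0.364 to 0.455 in replicate 2, and the second from 0.576 to 0.684 and from 0.554 to 0.693. Neither explanation, nor both together, thus reached the autosomal density under these assumptions. Repeats and mappability of X stay open and were not tested, and no biological explanation was tested beyond the numbers of genes and of copies.

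Footprints held fewer GATA, NKX2 and MEF2 motifs than the rest of the peaks, and footprints were richer in G and C. Base composition may contribute, since the reversed motifs were also less frequent, at -0.86 and -1.05 for GATA, -0.57 and -0.81 for NKX2 and -0.91 and -0.94 for MEF2. The mean difference between motif and reversed motif was -0.21 for GATA, 0.13 for NKX2 and 0.25 for MEF2, and the last was 0.63 in replicate 1 and -0.13 in replicate 2. For these motifs composition cannot be told apart from other causes. The GATA control is also not separate from the motif, because AGATAGA holds a match of the motif and of its reversal. For GATA (-0.22 and -0.20, with intervals off 0) and NKX2 the differences were below the 1.5-fold set in advance. For MEF2 the difference was past it in replicate 1 alone and unlike in the 2 libraries. The sequence preference of DNase I and brief binding were not tested, and no biological explanation was tested.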
